A study of Caenorhabditis elegans with 2 samples.

How the data were processed

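ChIP-seq was carried out on whole L3 larvae of a C. elegans strain with an integrated transgene that expresses eGFP-tagged ZTF-4, in 2 biological replicates that form 1 group. Library fragments were selected at 150 to 350 bp, per the labels. Peak lists in narrowPeak form were used. The deposited inventory text states that 1 list was called on the alignments of each replicate and 1 on the alignments of both together, each against a control, and that the IDR list was made from these. The peak caller, the aligner, the IDR threshold, their versions and the strain of the control were not given in the sources used here. Lists exist in the ce11 and ce10 builds, per the labels; ce11 was used throughout and ce10 as an alternative, with no conversion between builds.

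Each region's signal value was taken as the authors' own measure of enrichment, since its exact definition was not given in the sources used here, and was used to describe, rank and select regions within a list. The deposited lists also give −log10 q-values, which had a ceiling shared by many regions (3.15 in the pooled list, reached by 2113 regions), so that signal and not q was used for ranking. The summit offset was taken as the authors deposited it. The p-value column held no values and was not used. The candidate lists are input to IDR and hold weak regions along with peaks: 2 of them end at 30000 regions. Signal sizes of different lists were not set against each other, since their scaling is not known. The only exception, in the closing section, sets the replicate ratio of mitochondrial pairs beside that of nuclear pairs. Median region widths were 376 bp in both replicate lists and 370 bp in the pooled and IDR lists. The IDR peaks covered 244 kb. In the IDR list 10 regions shared their interval with another region and had their own summit, and each was counted by its summit. Alignments, signal tracks and the control were not used here, so read depth is unknown and intervals cover counting error over regions or genes only.

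The ce11 sequence and Ensembl release 115 gene models of the same assembly were used (19985 protein-coding genes), with mitochondrial gene names from NCBI RefSeq. No region of the ce11 lists extended past a chromosome end. Coordinates are 1-based. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

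Replicate agreement was measured over regions matched one to one by reciprocally nearest summits within 100 bp, with 100000 random pairings, and over the 704 strongest regions of each list, with chance from 1000 circular shifts within chromosomes (100 shifts for the reciprocal overlap alternative). A summit counted as near a gene start within 500 bp of the 5' end of a protein-coding gene, and shares were set against pooled candidates that did not pass IDR and against 1000 random placements on the same chromosomes. The X share was tested against the same candidates. For gene lists, genes with an IDR summit within 500 bp of the 5' end were compared with genes that had only other candidate summits there. Lists by biotype (tRNA, snoRNA, snRNA and miRNA genes) were compared with protein-coding genes. Presence of each of 2080 6-mers (with its reverse complement) within 50 bp of summits was compared with equal windows centred 300 bp to either side. Tests were 2-sided Fisher's exact tests with Woolf 95% intervals of odds ratios and Benjamini-Hochberg adjustment within each family, at 0.05. Summits were classed in the order coding exon, 5' UTR, 3' UTR, intron, non-coding gene, intergenic.

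The comparisons, the 33 gene lists and the rule for named items were fixed before the data were examined. Named were the 25 IDR peaks with the highest signal, each with the protein-coding gene with the nearest 5' end (all within 500 bp at diverging genes), ztf-4 and unc-119, up to 4 members per list by signal, the 5 higher 6-mers with the smallest p and the 2 lower ones. For mitochondrial peaks the gene at the summit is given. The classes of annotation, the comparison of odds ratios between X and autosomes, the GC content, the candidates inside gene models against windows of the same length, and the words of 8 and 10 bases in the closing section were added after seeing the data. For the 8-base word the choice was allowed for by Benjamini-Hochberg adjustment over all 8-mers, by 1000 permutations of which of each X peak's 3 windows was the summit, with the smallest p over all 8-mers taken each time, and by 1000 shuffles of the bases of each X summit window.

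Alternatives were a 50 bp summit distance, reciprocal overlap of 50%, regions at IDR peaks only, 352 top regions, ce10 lists, distances of 250 and 1000 bp, all transcripts' 5' ends, the 352 strongest IDR peaks, each replicate's own 704 strongest regions, chromosome length or all annotated genes as background, each region counted once, a window of 100 bp around summits, and candidates near 5' ends as the 6-mer background. Nuclear chromosomes alone and the mitochondrial genome alone were added after seeing the data.

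The procedures were tested on simulated data. In random genomic windows 0 of 2080 6-mers passed, and a 6-mer planted in 15% of 704 windows ranked 1. Both sets of random windows were drawn alike, so calls that arise from unlike base composition were not tested. With 1 of 33 gene lists raised, that list ranked 1 and was the only one to pass, and 0 passed with none raised. A simulated Pearson's r of 0.5 over 5000 pairs was recovered as 0.487.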

Results

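Chromatin bound by ZTF-4, a C. elegans protein named for its zinc finger domain, was profiled by ChIP-seq in L3 larvae, the third larval stage. The animals carried an integrated transgene that expressed ZTF-4 fused to eGFP, in an unc-119 mutant background. There was 1 group with 2 biological replicates of whole animals of both sexes. The data were lists of regions in the ce11 build, each with a signal value and a summit, the base of strongest enrichment. Replicate 1 had 29249 candidate regions, replicate 2 had 30000, and the list called on both replicates together (pooled) had 30000. The list thresholded by IDR, the irreproducible discovery rate computed from replicates, held 704 peaks, called IDR peaks from here on. Read numbers were not given with the lists, so the depth behind each region is unknown.

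The highest signals in the IDR list lay in the mitochondrial genome and upstream of ribosomal protein genes. Of the 25 IDR peaks with the highest signal, 20 were mitochondrial and 5 were nuclear. The strongest peak of all had its summit at position 4749 of the mitochondrial genome, inside the cytochrome b gene CYTB (signal 1186, region 4418 to 4915). The next had its summit at 12582 inside the NADH dehydrogenase subunit gene ND5 (signal 799.5), followed by summits at 5803 in COX3 (405.4) and 8645 in COX1 (400.2), genes for cytochrome c oxidase subunits. The strongest nuclear peak lay upstream of rpl-3, a large-subunit ribosomal protein gene (signal 265.4, rank 11). It spanned chromosome III 3867445 to 3867714, with the summit in intergenic sequence 271 bp upstream of the annotated 5' end.

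The other 4 nuclear peaks among the leading 25 were also intergenic. One on chromosome IV, 4749946 to 4750181, had signal 177.6 and lay between the diverging genes rpl-20, 287 bp away, and Y17G9B.5, 175 bp away. Another on chromosome IV, 654827 to 655039, had signal 170.5 and lay 357 bp from the 5' end of rpl-15 and 457 bp from that of K11H12.8. A peak on chromosome II, 10563450 to 10563685, lay 157 bp upstream of cdc-48.1 (signal 158.6), which encodes an AAA ATPase. The last, on chromosome I, 4172307 to 4172572, had signal 152.1. Its nearest protein-coding 5' end was that of egg-5 at 789 bp. Its summit lay 172 bp downstream of the 5' end of sls-2.4, an SL2 spliced leader RNA gene, and past that gene's 3' end. In each replicate's own list these 5 regions ranked between 5 and 29.

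Of the 28 pooled candidate regions in the mitochondrial genome, 26 were IDR peaks, or 92.9%, against 1.63% to 2.62% on each nuclear chromosome. The 26 mitochondrial peaks had a median signal of 218.2, and the 678 nuclear peaks a median of 45.6 with a maximum of 265.4. Of the 26, 20 had a partner in replicate 1, at ranks from 1 to 7572 (17 among its 704 strongest regions), and 24 in replicate 2, at ranks from 1 to 2938 (22 among the strongest). Summits fell in the genes for ND6, ND1, ATP6, ND2, CYTB, COX3, ND4, COX1, COX2, ND3 and ND5, in rRNA genes and in tRNA genes. IDR peaks covered 59.5% of the mitochondrial genome, and pooled candidates 62.7%, more than in any of 7266 nuclear windows of the same length (at most 57.2%). The leading 6-mer at all summits, GACGCA, occurs 0 times in the mitochondrial genome, which is 23.8% GC, and the reads of the control were not used here.

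**Figure D1:**
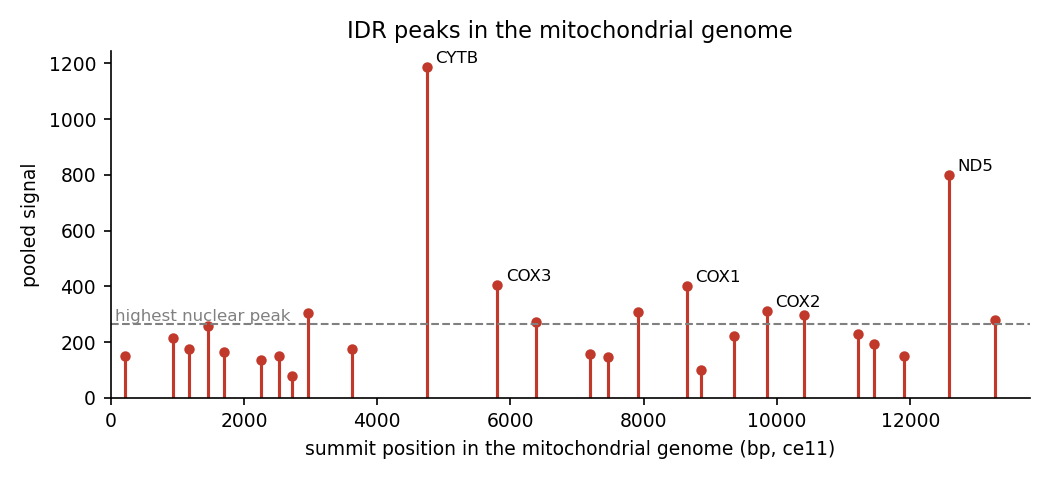
Each stem is 1 of the 26 mitochondrial IDR peaks, placed by its summit in base pairs (horizontal axis) with its pooled signal (vertical axis, the caller's units). The dashed line marks the strongest nuclear peak, at 265.4, and the 5 strongest mitochondrial peaks carry the name of the gene at the summit.

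How far the replicates gave the same regions was asked first over all candidate regions. The regions upstream of rpl-3, rpl-15 and cdc-48.1 were strong in both lists, with replicate 1 ranks of 5, 15 and 24 and replicate 2 ranks of 13, 24 and 25. Most weak regions had no partner: 6103 pairs had reciprocally nearest summits within 100 bp, 20.9% of the replicate 1 list and 20.3% of the replicate 2 list. How many pairs would be this close by chance was not estimated. Across these pairs the signals were correlated (Spearman's rho 0.427, Pearson's r 0.526 on log2 signal, 2-sided permutation p = 1e-05 for both, the smallest that 100000 pairings can give). This correlation is across regions, which are not independent replicates. Among the 652 pairs whose replicate 1 region overlapped an IDR peak, rho was 0.266 (permutation p = 1e-05).

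**Figure D2:**
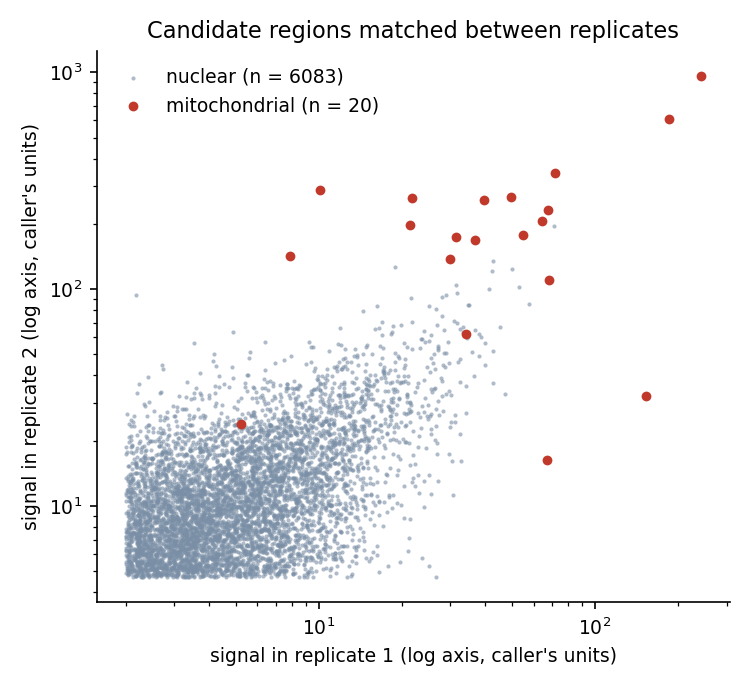
Each point is a pair of candidate regions with summits within 100 bp of each other, plotted by the signal in replicate 1 and in replicate 2 on log axes, in the caller's units. The 20 mitochondrial pairs include the strongest signals, and over the 6083 nuclear pairs alone rho was 0.422.

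Among the 704 regions with the highest signal in each replicate, 232 were shared, or 33%. Circular shifts of one replicate along each chromosome gave a mean of 11.6 and at most 20 shared regions in 1000 shifts (permutation p = 0.001, the smallest they can give). Without the mitochondrial genome, a setting added after seeing the data, 224 of 704 were shared against a mean of 1.06 by chance.

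The 704 IDR peaks were the 704 regions of highest signal in the pooled list, down to a signal of 35.9, and made up 2.35% of that list. Of these, 522 had a partner among the 704 strongest regions of replicate 2 and 363 among those of replicate 1. Anywhere in the replicate lists, 593 of the 704 had partners in both. In the older ce10 build the IDR list held 700 peaks.

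IDR peaks lay near gene starts more often than the other candidate regions did. Of the 704 summits, 282 (40.1%, Wilson 95% interval 36.5 to 43.7) were within 500 bp of the 5' end of a protein-coding gene, against 21.3% of the 29296 pooled candidates that did not pass IDR (odds ratio 2.47, 95% interval 2.12 to 2.88, 2-sided Fisher's exact p = 1.41e-28). Random placements on the same chromosomes gave a mean of 20.6% and at most 25.6% (permutation p = 0.001, the smallest that 1000 placements can give). The summits near gene starts were mostly on the upstream side, at 237 of 282 (84.0%, interval 79.3 to 87.9, 2-sided exact binomial p = 1.18e-32), and 73 of the 282 were within 500 bp of more than 1 gene's 5' end, as between rpl-20 and Y17G9B.5. The binomial test assumed equal shares on both sides of a 5' end. The upstream share of other candidates was not computed, so this is not an enrichment over them. Many C. elegans transcripts are trans-spliced, so an annotated 5' end can lie downstream of the true transcription start. These tests treat regions as units and do not measure variation between animals.

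By annotation, 375 of the 704 summits (53.3%) were intergenic, against 37.5% of the candidates that did not pass (odds ratio 1.90, adjusted exact p = 2.25e-16). Non-coding genes held 59 summits (8.38% against 2.38%, odds ratio 3.75, adjusted exact p = 1.84e-15). Introns of protein-coding genes held 161 (22.9% against 37.8%, odds ratio 0.489, adjusted exact p = 2.25e-16) and coding exons 59 (8.38% against 15%, odds ratio 0.519, adjusted exact p = 3.42e-07). Shares in 5' UTRs (2.56% against 1.86%, adjusted exact p = 0.243) and 3' UTRs (4.55% against 5.52%, adjusted exact p = 0.315) did not pass. These are Fisher's exact tests with Benjamini-Hochberg adjustment over 6 classes. The counts include the 26 mitochondrial peaks, whose summits lay in coding, rRNA and tRNA genes, against 2 mitochondrial regions that did not pass. Nuclear shares were not computed separately.

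**Figure D3:**
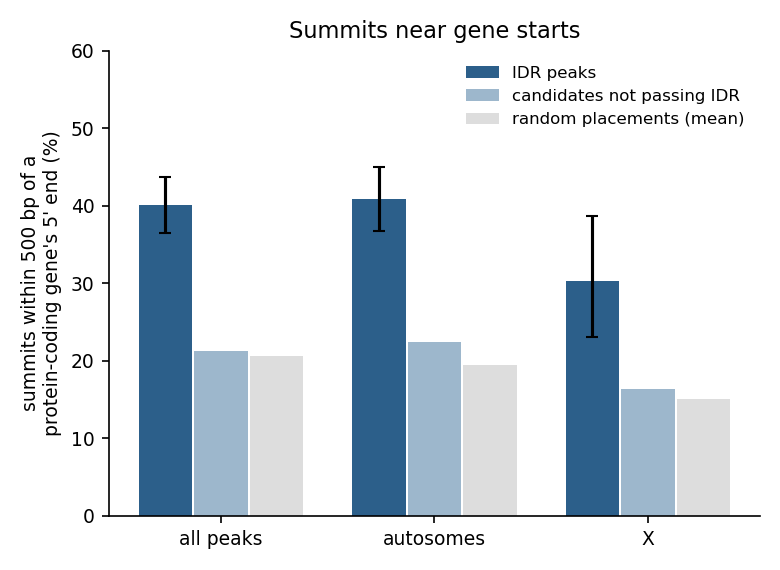
Bars give the percentage of summits within 500 bp of a protein-coding gene's 5' end for all IDR peaks, for autosomes and for X, beside candidate regions that did not pass IDR and the mean of 1000 random placements. Error bars are Wilson 95% intervals for IDR peaks, and the IDR bars stand at 40.1%, 40.8% and 30.3%.

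The X chromosome, the sex chromosome on which C. elegans dosage compensation acts, did not differ detectably from other chromosomes in its share of IDR peaks. There were 132 on X, 18.8% of all (Wilson 95% interval 16 to 21.8), against 19.5% of the candidates that did not pass (odds ratio 0.952, interval 0.789 to 1.16, 2-sided Fisher's exact p = 0.665). The density on X was 7.45 peaks per Mb. It was 8.92 on III, 7.89 on I, 7.4 on II, 5.02 on V and 4.92 on IV. The strongest X peak lay 295 bp upstream of puf-9, a Pumilio-family RNA-binding protein gene, at 5841222 to 5841415 (signal 117.5), and was named after its value was seen. Of the X summits, 40 of 132 (30.3%) were within 500 bp of a protein-coding 5' end, against 16.3% of X candidates that did not pass (odds ratio 2.23, exact p = 7.68e-05). On autosomes the shares were 40.8% and 22.5% (odds ratio 2.38). The ratio of these odds ratios, X over autosomes, was 0.935 with a 95% interval of 0.617 to 1.42.

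Genes for cytosolic ribosomal proteins and translation factors had ZTF-4 peaks at their 5' ends more often than other genes. Whether the peaks behind this and the following list and 6-mer results are particular to ZTF-4 was not tested. No untagged control or map of sites where many factors are recovered was used here. Of 5719 protein-coding genes with any candidate summit within 500 bp of the 5' end, 343 (6%) had an IDR summit there. Among the genes for cytosolic ribosomal proteins the share was 25 of 72 (34.7%, Wilson 95% interval 24.8 to 46.2, odds ratio 8.91, adjusted exact p = 2.27e-12). In the strongest regions of replicate 1 alone the count was 14 of 68 (20.6%, odds ratio 5.11, adjusted exact p = 5.42e-05), and within 250 bp it was 6 of 33 (18.2%, odds ratio 3.97, adjusted exact p = 0.0488). Their strongest peaks were those of rpl-3, rpl-20, rpl-15 and rps-1, with signals of 265.4, 177.6, 170.5 and 134.8. Genes for mitochondrial ribosomal proteins did not stand out, with 1 of 41 (mrps-7, signal 36.1, adjusted exact p = 0.809). All adjusted exact p-values for lists are from 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 33 lists.

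Translation factor genes had IDR summits at 8 of 32 (25%, odds ratio 5.32, adjusted exact p = 0.00300). The leading members were iff-2 (signal 81.0), an eIF5A gene, eif-3.C (58.2), eef-2 (56.0) and eef-1G (55.8). Heat shock and chaperone genes had them at 9 of 38 (23.7%, odds ratio 4.97, adjusted exact p = 0.00257), led by the Hsp70 family genes hsp-1 (77.6) and hsp-3 (59.3), then dnj-13 (56.9) and the chaperonin subunit gene cct-8 (54). Oxidative phosphorylation genes had them at 7 of 38 (18.4%, odds ratio 3.59, adjusted exact p = 0.0311), led by the nuclear genes cox-5A (141.8), cox-5B (78.6), atp-1 (71.0) and asb-2 (43.4). The translation factor call was lost in the strongest regions of replicate 1 alone (5 of 27, adjusted exact p = 0.0547), and the chaperone call in those of replicate 2 alone (odds ratio 3.27, adjusted exact p = 0.06) and within 250 bp (odds ratio 2.78, adjusted exact p = 0.454). The oxidative phosphorylation call was lost in the strongest regions of replicate 1 alone (4 of 32, adjusted exact p = 0.244), within 250 bp (odds ratio 1.59, adjusted exact p = 0.797) and with the 352 strongest IDR peaks (adjusted exact p = 0.508).

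Genes for small structural RNAs also carried ZTF-4 peaks more often than protein-coding genes did. Small nucleolar RNA (snoRNA) genes, whose products guide rRNA modification, had IDR summits at 48 of 199 (24.1%, Wilson 95% interval 18.7 to 30.5, odds ratio 4.98, adjusted exact p = 2.06e-14), and at 31 of 200 in the strongest regions of replicate 1 alone (15.5%, odds ratio 3.48, adjusted exact p = 1.91e-06). Of these 48 genes, 25 lay inside a protein-coding gene. The leading members were C06A1.9 inside cdc-48.1 (signal 158.6), F54E7.10 inside rps-12 (98.3), ZK994.7 inside pxn-1 (88.2) and W06H8.17 (73.6). The peak of C06A1.9 was that 157 bp upstream of cdc-48.1, with its summit 500 bp from the snoRNA gene's 5' end. The summit for F54E7.10 lay 145 bp from the 5' end of rps-12 and 225 bp from that of the snoRNA gene. The 48 genes were served by 46 peaks, of which 15 were also within 500 bp of a protein-coding 5' end and 3 of a ribosomal protein gene's. Small nuclear RNA (snRNA) genes had them at 9 of 47 (19.1%, odds ratio 3.71, or 6.54 within 250 bp, adjusted exact p = 0.0101 and 5.93e-04), led by the SL2 genes sls-2.4 (152.1) and sls-2.2 (95.7), R07E5.16 (79.7) and F38E11.11 (64.7). The summits for sls-2.4 and sls-2.2 lay past the 3' ends of these genes.

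Genes for tRNAs had IDR summits at 66 of 436 (15.1%, odds ratio 2.80, adjusted exact p = 9.08e-10), of which 22 were mitochondrial tRNA genes. The 4 leading members were mitochondrial tRNA genes between 4269 and 4502 next to the peak in CYTB. On nuclear chromosomes alone, a setting added after seeing the data, the share was 44 of 414 (10.6%, odds ratio 1.93, adjusted exact p = 0.00217). The 44 nuclear genes were served by 35 peaks, 31 of them with the summit within 100 bp of the tRNA gene's 5' end. For miRNA genes the count was 9 of 108 (adjusted exact p = 0.670), led by cel-mir-54, cel-mir-55 and cel-mir-55b on X at 1 shared peak (signal 53.7) and cel-mir-5549 (49.2).

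Splicing factor and RNA-binding protein genes and chromatin regulator genes each had 7 of 44 (15.9%, odds ratio 3.01), with adjusted exact p = 0.0540 for both. The first were led by fust-1 (signal 63.4), spk-1 (48.7), hrpk-1 (47.8) and rbm-39 (47.5). The chromatin regulators were led by lin-54 (89.1), a DREAM complex gene whose peak summit lay 356 bp from its 5' end and 37 bp from that of the ribosomal protein gene rpl-12, set-16 (88.2), ash-2 (62.6) and met-1 (60.9). On nuclear chromosomes alone both lists passed. Histone genes had 3 of 15 (adjusted exact p = 0.188), namely his-37 (92.6) and the neighbours his-67 and his-68 at 1 shared peak (45.3).

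None of the lists of tissue-restricted genes, signalling pathway genes and aminoacyl-tRNA synthetase genes differed from other genes at an adjusted p of 0.05. Pan-neuronal genes had 2 of 18 (11.1% against 5.98% of other genes), unc-14 (signal 49.6) and snb-1 (37.7), and cuticle collagens 1 of 51, col-38 (36.2). The peak of col-38 was also that of the ribosomal protein gene rpl-5. There were 0 for body wall muscle (of 19), hypodermis and seam (of 19), germline (of 11), intestine (of 8), pharynx (of 2), major sperm proteins (of 2), neuropeptides (of 27), the Wnt, Notch, TGF-beta and EGF pathways (of 27) and aminoacyl-tRNA synthetases (of 17). A count of 0 allows up to 12.5% of 27 genes and up to 65.8% of 2 genes (Wilson 95% upper limits), so lists this small could not show a depletion.

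Transcription factor families did not differ detectably from other genes. Nuclear hormone receptors had 5 of 98, led by nhr-47 (signal 49), nhr-1 (48.4), nhr-68 (46.4) and nhr-49 (40.8), homeobox genes 1 of 19, ceh-38 (49.4), and ztf genes 1 of 11, ztf-7 (57.5). Insulin and stress factors had 1 of 20, again nhr-49. Cell cycle and DNA replication genes had 3 of 24, rfc-4 (49.2), mdf-1 (38.3) and pcn-1 (37), the vacuolar ATPase 2 of 15, vha-1 (46.3) and vha-12 (41.5), and the proteasome 1 of 24, rpn-3 (52.2). Chemoreceptor genes had 3 of 90, srh-269 (47.5), sri-5 (39.2) and srh-16 (36.9), and were lower only with all annotated genes as background (0.229% against 1.82%, adjusted exact p = 2.59e-06). The F-box, BATH and MATH genes had 2 of 32, fbxb-72 (52.6) and fbxb-85 (40.7), and C-type lectins 2 of 12, clec-126 (45.8) and clec-221 (38). With the main background the adjusted exact p-values of these lists lay between 0.471 and 1. Some of their peaks were shared with members of lists that passed. The peak of nhr-47 was also that of dnj-19, that of rfc-4 also that of eef-1A.1, and that of rpn-3 also that of hsp-110. The peaks of srh-269 and clec-126 were also those of tRNA genes.

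**Figure D4:**
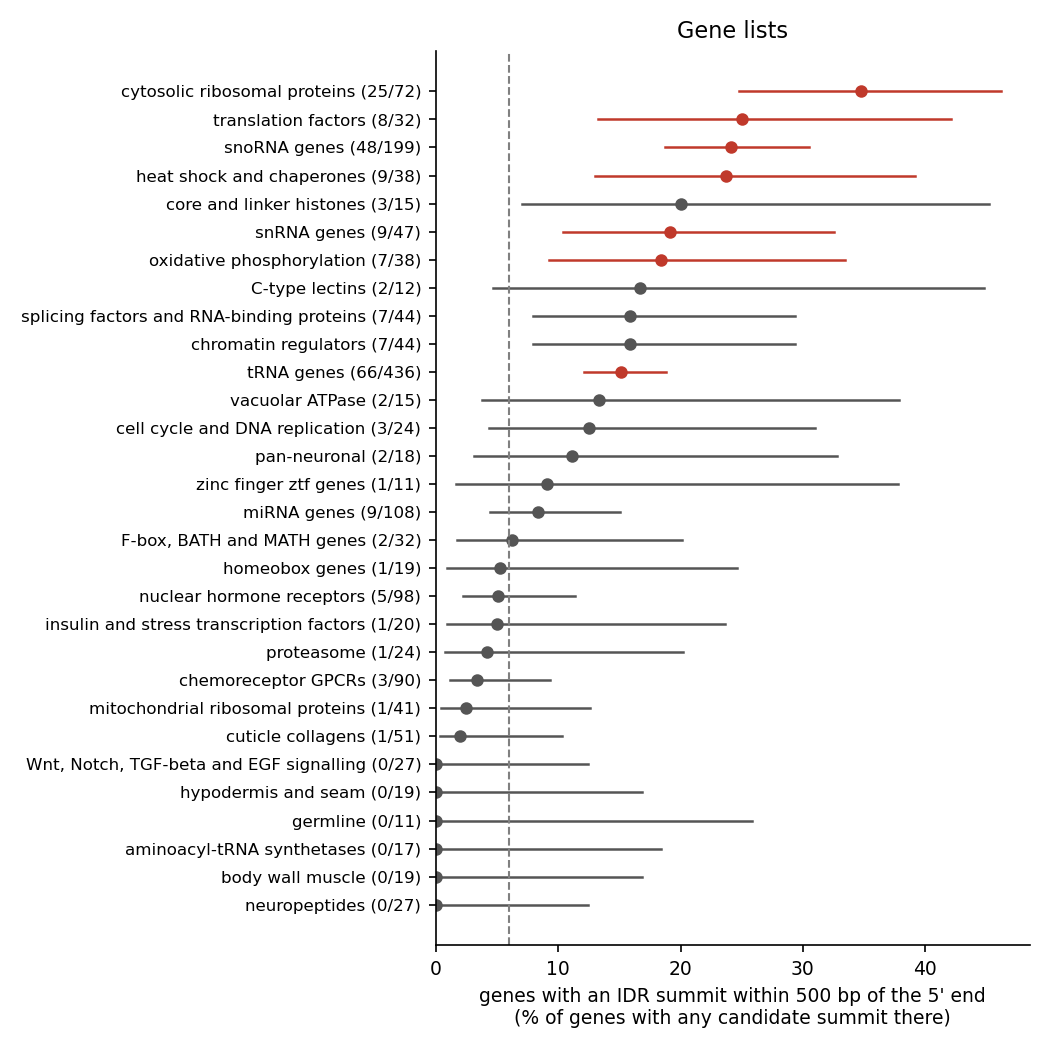
Points give the percentage of each list's genes that had an IDR summit within 500 bp of the 5' end, out of those with any candidate summit there (both numbers in brackets), with Wilson 95% intervals as lines; lists with under 10 such genes are left out. Red marks the 7 lists past an adjusted p of 0.05, and the dashed line the 6% of all protein-coding genes.

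ZTF-4 summits were marked by GC-rich short sequences that were rare 300 bp away. GACGCA or its reverse complement TGCGTC was present within 50 bp of 15.6% of summits and in 1.92% of flanking windows (odds ratio 9.46, 95% interval 6.08 to 14.3, adjusted exact p = 3.58e-28). The next were ACGCAG (15.9% against 2.2%, odds ratio 8.40), AGAGAC (18.9% against 4.33%, odds ratio 5.14), AGACGC (13.4% against 2.13%, odds ratio 7.07) and AGAGAG (19.5% against 5.19%, odds ratio 4.41), with adjusted exact p-values from 3.22e-27 to 1.04e-20. A/T-rich 6-mers were rarer at summits, led by AAAAAT (23.4% against 45%, odds ratio 0.374, adjusted exact p = 4.91e-20) and TTAAAA (9.66% against 27%, odds ratio 0.289, adjusted exact p = 1.78e-19).

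In all, 389 of 2080 6-mers were more frequent at summits and 213 less frequent (2-sided Fisher's exact test with Benjamini-Hochberg adjustment over all 6-mers). In the strongest regions of replicate 2 alone the numbers were 248 and 127. The windows also differed in base composition: the mean GC content was 44.7% ± 10.2 (SD, n = 704 windows) at summits and 35.5% ± 8.75 (SD, n = 1407) in flanks. Against 6232 candidate regions near 5' ends that did not pass IDR, GACGCA stood at 15.6% and 4.44% (odds ratio 3.98, adjusted exact p = 3.21e-23), ACGCAG had an odds ratio of 4.08 and AGACGC of 3.75. The mean GC content of these candidate windows was 35.9%, near that of the flanks. Neither background matched the base composition of summits, so its part in these differences was not tested. In the strongest regions of replicate 1 alone GACGCA was at 11.7% of summits and 3.13% of flanks (odds ratio 4.09, adjusted exact p = 1.01e-11), and the odds ratios of ACGCAG, AGACGC and AGAGAC were 4.52, 4.24 and 3.35.

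**Figure D5:**
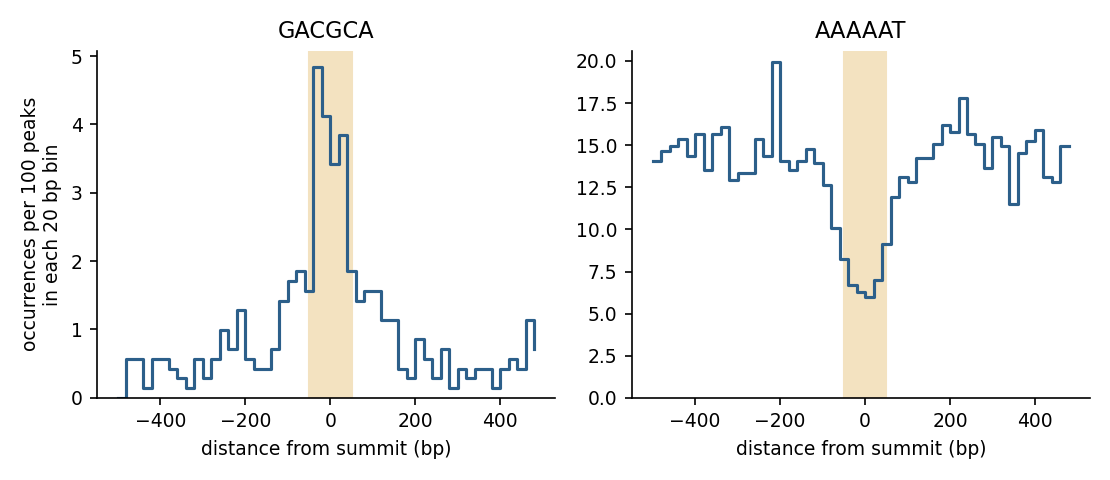
Lines give the number of occurrences of GACGCA (left) and AAAAAT (right), on either strand, per 100 IDR peaks in each 20 bp bin, against the distance from the summit in bp. The shaded band is the tested window within 50 bp of the summit, where GACGCA rose to 4.84 per bin and AAAAAT was at its lowest.

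The loci tied to the transgene were examined as a check of the labels, since extra gene copies can change signal there. The ztf-4 gene (chromosome I, 6926257 to 6929665) had no IDR peak within 20 kb and 2 weak pooled candidate regions, the better at rank 21700 with signal 7.50, where a span of this length held 13 candidates on average. No candidate summit of any of the 3 lists lay inside the gene, as in 52% of nuclear windows of its length in the pooled list, so no enrichment at the tagged locus was seen. The unc-119 gene (chromosome III, 10902641 to 10908935), needed for neuronal development and movement, had 14 pooled candidates within 20 kb against an average of 13.9. Inside the gene model there were 6, against an average of 1.88 for its length, and 8.55% of nuclear windows of that length held as many (8 candidates and 2.17% in replicate 1, 7 and 4.88% in replicate 2). The best, inside the gene model, had rank 1189 and signal 29.4, below the weakest IDR peak, and the best regions of replicates 1 and 2 had ranks 1046 and 654.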

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

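The nuclear-only and mitochondrial-only settings were chosen after seeing the data. Of 42 alternatives to the comparisons, 35 left the call or count in place. The share of summits near gene starts stayed above that of other candidates under all 7 alternatives, and the X share missed the threshold under all 5. Replicate rank agreement was 0.280 (permutation p = 0.231) over the 20 mitochondrial pairs alone, where the small number of pairs limits the test. The shared part of the top regions was 24.3% with summits within 50 bp, a stricter match, and 31.8% to 35.5% under the other alternatives. This comparison was fixed as a count, and a share was used across alternatives only after the counts were seen: as a count, the alternative with 352 top regions would lie outside 1.5 times the 232, and the 171 within 50 bp would not. IDR peaks with a partner among the strongest regions of 1 replicate numbered 363 without replicate 2 and 522 without replicate 1. The number of 6-mers higher at summits was 252 with the 352 strongest peaks, where fewer windows were tested, and 248 to 286 in the single-replicate lists, where the cause was not tested; 225 and 234 of these were among the 389. The number lower was 213, with 149 for the 352 strongest peaks and 127 to 162 in the single-replicate lists. Inside the gene models alone, a shorter span, there were 0 candidates at ztf-4, where the mean over the genome is 1.02 and 52% of nuclear windows of that length hold 0, and 6 at unc-119, where the mean is 1.88 and 8.55% hold as many. Between 5 and 9 gene lists were higher across settings. With all annotated genes as background the odds ratios of 6 of the 7 lists that passed rose by over 1.5 times, to between 6.65 and 27, and chemoreceptor genes were lower (odds ratio 0.124, adjusted exact p = 2.59e-06), the only list lower in any setting. With the 352 strongest peaks, where fewer genes can have one, 33 tRNA and 24 snoRNA genes did, and the odds ratio of the chaperone list was 7.84. Of 56 alternatives for the 7 lists that passed, 50 kept the call and 6 lost it with the same direction, all for translation factors, chaperones or oxidative phosphorylation. Chromatin regulators, outside the 7, passed in several settings, among them 1000 bp and the 352 strongest peaks. The 7 named 6-mers kept direction and call under all 42 alternatives, though the odds ratio of GACGCA was 6.02 within 100 bp of summits, that of ACGCAG 14.2 with the 352 strongest peaks and that of TTAAAA 0.447 in the strongest regions of replicate 2 alone. No paired analysis was possible because there is 1 group. Read depth is unknown, and fewer IDR peaks had a partner among the strongest regions of replicate 1 than of replicate 2, which limits what can be said of weak peaks.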

Other observations

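All tests in this part were chosen after the results were seen. The leading 6-mers GACGCA, ACGCAG and AGACGC all lie within the 10-base word GAGACGCAGA. It was present within 50 bp of 50 of 704 IDR summits (7.10%) and in 3 of 1407 flanking windows (0.213%), counts that describe but do not test it, since the word was put together from 6-mers found in these same windows. On autosomes it was at 42 of 546 summits (7.69%) and on X at 8 of 132 (6.06%), a difference that did not pass (exact p = 0.710). Autosomal candidates that did not pass IDR had it at 0.967% of summits and 0.467% of flanks (exact p = 1.66e-14). Of the 50 nuclear IDR peaks with the word, 26 (52%) were near a protein-coding 5' end, against 37.7% of the others (exact p = 0.0508), with 19 of 42 against 40.5% on autosomes (exact p = 0.625) and 7 of 8 against 26.6% on X (exact p = 9.73e-04), where only 8 peaks had the word.

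An 8-base word was more frequent at X summits than at autosomal ones. GCGCAGGG is part of a motif known from the sites that recruit the dosage compensation complex to X, and was picked from background knowledge of that motif after the positions of the X peaks and the 6-mers had been seen. To allow for this choice, all 32896 8-mers were compared. GCGCAGGG was at 9 of 132 X summits (6.82%) and 1 of 546 autosomal summits (0.183%, odds ratio 39.9, Fisher's exact p = 2.68e-06, adjusted exact p = 0.0440 over all 8-mers), and only the overlapping CGCGCAGG had a smaller p (10 and 1 summits, adjusted exact p = 0.0178). The 9 X peaks included summits at 8036417 (signal 116.8), 340 bp from the 5' end of a tRNA gene and 4896 bp from that of xol-1, the X-dose switch gene of sex determination, at 11094185 (115.3), 14525949 (110.2) and 4209278 (108.1). Of the 10 nuclear peaks with the word, 0 lay within 500 bp of a protein-coding 5' end, against 39.4% of the others (exact p = 0.00828). Among X peaks alone the shares were 0 of 9 and 32.5%, a difference that did not pass (exact p = 0.0566). GC composition is argued against as the source: with the bases of each X summit window shuffled, no 8-mer made of the same bases was in more than 5 windows in 1000 shuffles (permutation p = 0.001). In the flanks of the same peaks 1 of 264 windows had the word (permutation p = 0.0390, allowing for the choice among all 8-mers). These flanks were lower in GC, at a mean of 35.1% against 47.3% at X summits. The comparison therefore cannot decide whether the sequence of X at large is the source. Among candidates that did not pass IDR the word was rare but more frequent on X. It was at 0.105% of X summits and 0.044% of their flanks (exact p = 0.197), and at 0.0212% and 0.017% on autosomes. A candidate explanation is that tagged ZTF-4 was recovered at dosage compensation sites, or at sites where many factors are recovered, and no biological explanation was tested because no map of either was used here.

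The 26 mitochondrial IDR peaks could come from a difference in mitochondrial DNA content between the ChIP and control libraries. Candidate regions covered 62.7% of the mitochondrial genome, and none of 7266 nuclear windows of the same length reached this, with a median of 8.05% and a maximum of 57.2%. This coverage restates the crowding of the peaks and would also follow from binding at many sites, so it does not favour either explanation. Over matched regions, the median ratio of replicate 2 to replicate 1 signal was 4.57 for 20 mitochondrial pairs (quartiles 3.21 to 5.78). For 6083 nuclear pairs it was 2.16 (1.46 to 3.16). The mitochondrial pairs include the strongest signals. Whether the ratio changes with signal was not tested, so the cause of the higher mitochondrial ratio stays open. The signals of the 26 peaks were uneven, from 79.0 to 1186. The exact definition of the signal is not known and read coverage was not examined, so this unevenness does not favour either explanation. Binding at the leading 6-mer is argued against, since GACGCA occurs 0 times on either strand of the mitochondrial genome, which is 23.8% GC. This says nothing of binding at other sequences, which stays open, since the control's reads were not used here and no biological explanation was tested.

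A stretch that holds ztf-4 and reaches further to its right than to its left had no candidates, with 2 weak pooled ones at or beyond its left edge within 20 kb of the gene. The gap ran from 6909845 to 6962029 on chromosome I in the pooled list (52.2 kb), and from 6909844 to 6961300 and from 6912325 to 6962030 in replicates 1 and 2. A gene-poor region is argued against, since 15 protein-coding 5' ends lay in the gap (percentile 86.1) and the median of windows of that length on the chromosome was 9.5. An excess of masked repeats was not seen. They made up 32.2% of the gap against a median of 34.9%, at percentile 40.6 of those windows. A candidate explanation is extra copies of the tagged clone in the control. They would lower the ratio there only if the ChIP library held fewer copies, and the ChIP animals carried the transgene themselves. This explanation cannot be told apart from chance. In the pooled list 13.9% of nuclear protein-coding genes lay in a gap as long, and 2.41% and 11% in replicates 1 and 2. For the central part of chromosome I the shares were lower, at 3.78% (pooled), 1.74% and 2.76% (replicates 1 and 2). The strain of the control was not given in the sources used here.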
